A study of Mus musculus with 8 samples.

How the data were processed

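The samples were total RNA from primary cardiac endothelial cells of mice lacking the LDL receptor, either with Pparg deleted by a Tie2-Cre transgene (knockout) or without the deletion (control). Cells were taken on chow, at 0 weeks of atherogenic diet and 13 weeks of age, or after 2 weeks of the diet, at 15 weeks of age. Each of the 4 groups had 2 arrays, and each array held RNA pooled from 5 hearts, so a replicate is a pool and the spread between arrays is the spread between pools. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with DNase I, amplified to biotinylated cRNA and hybridised to an Illumina bead array. All 8 arrays came from 1 chip whose positions follow the groups, and age rises with diet, so chip position and age could not be separated from the groups.

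Per the file headers, the deposited table gives for each probe and array a mean bead intensity, a detection p-value, the number of beads and the standard error of the bead intensities. The submitters' processing notes name GenomeStudio; its version is not given in the sources used here. The deposited intensity values were not normalized, with lowest values of 82.7 to 90.3 per array, so no background had been subtracted from them. The detection p-value, per the deposited values, moves in steps of a 798th. The bead count per probe, also deposited by the authors, had a median of 40 or 41 on each array. The authors' second table holds normalized intensity on a linear scale. Its column medians were between 169.8 and 169.9, and its rank order within each array matched the non-normalized intensity (Spearman rho across probes 1.00); the method that made it is not given in the sources used here. It served as an alternative.

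The intensities were background-corrected with the normexp model, given an offset of 16, quantile-normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, which infers the negative controls from the detection p-values. A probe was tested if its detection p was under 0.05 on at least 2 of the 8 arrays, which kept 13502 of 25697 probes and 9366 genes. Of all probes, 23978 had 1 gene symbol in the platform annotation, 1719 had none and 0 had several; 23962 were matched by gene ID to RefSeq genes of the assembly GRCm38.p6, and 0 symbols changed. Where a gene had several probes, gene lists used the probe with the highest mean level.

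A linear model with 1 mean per group was fitted to all 8 arrays with lmFit and eBayes (4 residual and 7.54 prior degrees of freedom). It gave the effect of genotype on each diet, of diet in each genotype, their interaction (diet change in knockout minus diet change in control) and the genotype effect averaged over the diets. Calls are probes with a Benjamini-Hochberg adjusted p under 0.05 over all tested probes. With no change, 675 of the 13502 tested probes would have an unadjusted p under 0.05. Log2 changes are given ± the model's standard error, with n = 2 arrays per group, and levels ± SD. The 30 gene lists, covering endothelial function, PPARγ targets, prostanoids, lipid and energy metabolism, stress responses and markers of other cell types, were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 30 lists. Camera with an estimated correlation and fry (which tests whether a list moves 1 way on balance) were run beside it. The lists, the comparisons, the alternatives and the naming rule were fixed before the data were examined.

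The named genes were Pparg in every array, then, per comparison of groups, the 12 largest rises and the 12 largest falls among calls for which both arrays of a group lay above both arrays of the other. Only genes with a symbol other than a clone or predicted name counted. Each was given by the brightest of its passing probes, so the probe can differ between comparisons. Where fewer than 5 passed, the genes with the 8 smallest p-values in each direction, passing genes included, were named. Those that did not pass were said not to pass. The interaction used 8 each way, and up to 4 members of each list with the smallest p were added. Where a group had no array with a detection p under 0.05, a fold is given as "at least": the detected group's mean over the mean of, per array, the higher of the lowest detected level and the probe's own level.

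The number of arrays limits the precision of every value. The steps were tested on simulated data; the simulation was revised after its first run, because its undetected probes were too bright and too many passed the filter. In a simulated comparison of genotype on chow over 14466 probes, with changed probes at 4 fold sizes, the test recovered 0% of 50 changed 1.5-fold, 12% of 50 changed 2-fold, 70% of 50 changed 3-fold and 82% of 50 changed 4-fold, with 5 false calls. A separate simulation with nothing changed tested 14273 probes and gave 0 calls. In the same simulated comparison a list of proliferation genes raised 2-fold passed camera with the preset correlation (adjusted p = 5.36e-21) and not with the estimated correlation (adjusted p = 0.0889). The simulated genes varied independently, so this does not show which setting suits genes that vary together. Values for overlaps between comparisons were set beside 20 simulations of unchanged groups, in which every probe varied independently. Every simulated group also had the same spread per probe. This fixes the simulated correlation in advance, both for comparisons that share no array and for those that share a group.

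The alternatives were no background correction, median scaling, the authors' normalized table, an offset of 50, no filter, a strict filter (detection p under 0.01 on every array of at least 1 group), a block for the replicate number, only the compared groups' arrays, eBayes with trend and robust estimation, and leaving out each array. Array weights were added after seeing the data. Figures were drawn with matplotlib 3.10.9.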

Results

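The study measured gene expression in primary cardiac endothelial cells of LDLr-/- mice, which lack the receptor that clears LDL and are used to model atherosclerosis. Its title names endothelial activation and prostacyclin as the processes of interest for Pparg, a lipid-activated nuclear receptor. The Tie2-Cre transgene used for the deletion is active in endothelial cells and also in many blood cells. The 4 groups had 2 arrays each: control on chow, knockout on chow, control on atherogenic diet and knockout on atherogenic diet. Between 46.8% and 49.5% of probes were detected per array. The mean deposited intensity was 707 and 731 on the control chow arrays and lay between 842 and 923 on the other 6. Endothelial transcripts were bright: Aqp1, a water channel, had group means of 15.37 to 15.56 on the log2 scale and Egfl7, secreted by endothelium, of 15.35 to 15.66. Transcripts of other cells were bright too. In control chow, Dcn, the fibroblast proteoglycan decorin, had a mean of 15.30 and Hba-a1, alpha globin, of 13.99.

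The control chow arrays stood apart from the rest. The first principal component held 49.1% of the variance and placed them at −46.1 and −33.0, and the other 6 arrays between −0.0035 and 28.1. Correlations across probes, which are not independent replicates, were 0.982 to 0.992 within groups and 0.952 to 0.990 between groups.

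**Figure D1:**
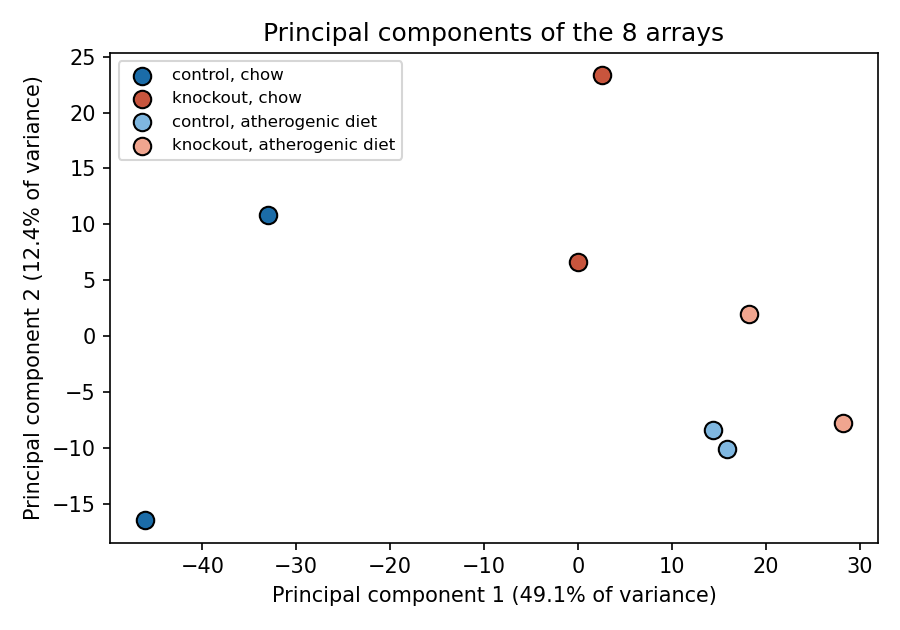
Scores of the 8 arrays (points) on the first 2 principal components of normalized log2 levels, with axes giving the share of variance (49.1% and 12.4%) and colours the group. The 2 control chow arrays lie at −46.1 and −33.0 on the first component.

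Pparg itself was measured by 2 tested probes, which differed in opposite directions on chow. Probe ILMN_1221594 was detected on all 4 control arrays and on 0 of 4 knockout arrays. On chow its log2 levels were 6.70 and 6.31 in control and 4.84 and 4.95 in knockout, and on the diet 7.45 and 7.11 in control and 4.86 and 5.07 in knockout. By this probe Pparg was at least 1.62-fold lower in knockout on chow (adjusted p = 0.0067) and at least 2.85-fold lower on the atherogenic diet (adjusted p = 7.44e-04). The brighter probe ILMN_1221060 was detected on every array. Its levels were 9.06 and 9.51 in control and 10.67 and 11.25 in knockout on chow, and 10.56 and 10.46 in control and 10.86 and 10.74 in knockout on the diet. It was higher in knockout by 1.67 ± 0.23 on chow (adjusted p = 0.0070) and differed by 0.29 ± 0.23 on the diet (adjusted p = 1.00). Another probe, ILMN_1221893, was detected on 0 arrays. Where the probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside it does not check the labels. With the diet, ILMN_1221594 rose in control by 0.77 ± 0.21 (adjusted p = 0.0353) and ILMN_1221060 by 1.22 ± 0.23 (adjusted p = 0.0069).

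**Figure D2:**
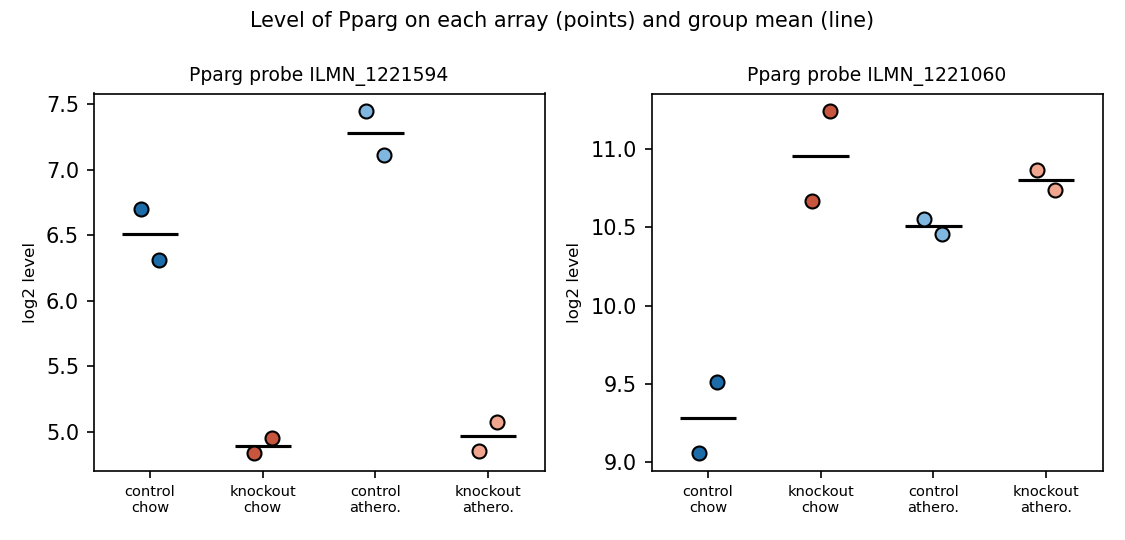
Normalized log2 level of Pparg on each array (points) and group mean (line) for probes ILMN_1221594 (left) and ILMN_1221060 (right); the vertical axes do not start at 0. By ILMN_1221594 the 4 knockout arrays lie between 4.84 and 5.07 and the 4 control arrays between 6.31 and 7.45.

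The first comparison asked what the deletion changed on chow. In knockout cells Ptgis, the synthase of prostacyclin, fell by 1.46 ± 0.22 on the log2 scale (adjusted p = 0.0093), Ptgs2, cyclooxygenase-2, fell by 1.81 ± 0.37 (adjusted p = 0.0234) and Slco2a1, a prostaglandin transporter, fell by 1.00 ± 0.23 (adjusted p = 0.0304). Ptges2, a prostaglandin E synthase, was at least 1.62-fold higher. In this prostanoid list 1 of 16 members rose and 3 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.865). Among genes of endothelial activation, Selp, encoding P-selectin, and the adhesion molecule Vcam1 fell by 1.55 ± 0.30 and fell by 0.95 ± 0.21, while the chemokine Cxcl9 rose by 0.91 ± 0.18 and Tnf by 1.21 ± 0.27. Of the 28 members of that list, 3 rose and 3 fell (3 and 4 adjusted over the list alone, with camera adjusted p = 0.503). Under the 18 alternatives Ptgis passed in 15, Ptgs2 and Vcam1 in 13 each and Selp in 12.

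Other named rises on chow were those of Thrsp, a lipogenic nuclear protein (2.21 ± 0.48), Hbb-bt, a beta globin (1.94 ± 0.27), Mt1, a metallothionein (1.90 ± 0.19), the retrotransposon-derived Rtl8a and Rtl8b (1.87 ± 0.33 and 1.80 ± 0.33), Depp1 (1.83 ± 0.39), the metalloproteinase inhibitor Timp4 (1.79 ± 0.45), Srarp (1.71 ± 0.31) and Ifi202b, an interferon-inducible gene (1.69 ± 0.41). Depp1 and Timp4 lie among the 20 tested genes on either side of Pparg. Fcgr4, an Fc receptor of myeloid cells, was at least 3.09-fold higher and S100a8, abundant in neutrophils, at least 1.84-fold higher; neither was detected in control on chow. Thrsp and Srarp were detected on 1 of 2 control chow arrays, and Slc7a2, among the falls, on 1 of 2 knockout chow arrays. Other named falls were those of Pla2g7, which hydrolyses platelet-activating factor (−1.99 ± 0.30), Slc18a2, a monoamine transporter (−1.78 ± 0.23), the matrix proteins Spon1 (−1.70 ± 0.23) and Comp (−1.65 ± 0.22), Sall1 (−1.66 ± 0.25), the muscarinic receptor Chrm3 (−1.65 ± 0.28), the estrogen receptor Esr1 (−1.63 ± 0.26), Evc (−1.63 ± 0.21) and the arginine transporter Slc7a2 (−1.62 ± 0.36). Cpxm1 was at least 2.23-fold lower. Knockout chow arrays differed in Timp4 and Ifi202b, with SDs of 1.33 and 1.04. Without replicate 1 and without replicate 2 of knockout chow, Timp4 was 2.73 and 0.85, Ifi202b 2.42 and 0.95 and Thrsp 2.82 and 1.58; without those of control chow Thrsp was 1.58 and 2.88. The genes of this paragraph passed under 11 (Depp1) to 17 (Mt1) of the 18 alternatives, Timp4 under 12 and Ifi202b and Thrsp under 13.

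Markers of other cells differed with the genotype on chow. Of 5 erythroid genes 4 rose (5 adjusted over the list alone), including Hbb-bt, Alas2 (1.60 ± 0.26) and Hba-a1 (1.39 ± 0.24), with camera adjusted p = 4.69e-06, and adjusted p = 0.334 with an estimated correlation. Of 16 smooth muscle and pericyte markers 5 rose (7 adjusted over the list alone), among them Notch3 (1.06 ± 0.23), Myh11 (0.89 ± 0.19) and Higd1b, at least 2.51-fold (adjusted p = 3.05e-05; adjusted p = 0.359 with an estimated correlation). Of 17 fibroblast markers 3 fell, Col3a1 (−1.07 ± 0.19), Lum (−1.07 ± 0.21) and Col1a2 (−0.97 ± 0.25); adjusted over the list alone, 1 rose and 9 fell (camera adjusted p = 3.42e-04, and adjusted p = 0.334 with an estimated correlation). Camera gave adjusted p of 0.397 for cardiomyocyte, 0.560 for macrophage, 0.612 for lymphocyte, 0.166 for neutrophil and 0.503 for mesothelial markers.

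Proliferation genes were higher in knockout on chow, with Tk1, Birc5, Cdk1 and Aurka called (0.96, 1.07, 0.89 and 0.68) among 22, and 8 adjusted over the list alone (camera adjusted p = 7.25e-06, and adjusted p = 0.334 with an estimated correlation). Interferon-stimulated genes were higher, with Rsad2 (1.02 ± 0.19), Oas2 (1.06 ± 0.20) and Cmpk2 (0.77 ± 0.20) called among 26, and 9 adjusted over the list alone (adjusted p = 1.33e-05, and adjusted p = 0.334 with an estimated correlation). Respiratory chain genes had a median of 0.29, with Ndufa4 called among 46 and 0 adjusted over the list alone (adjusted p = 3.07e-05, and adjusted p = 0.612 with an estimated correlation). Sterol efflux and LXR target genes were lower, with the apolipoproteins Apoc1 (−1.69 ± 0.29) and Apoe (−1.10 ± 0.23), the receptor Nr1h3 (−0.78 ± 0.17) and the desaturase Scd1 (−0.88 ± 0.21) called among 13. Adjusted over the list alone, 1 rose and 7 fell (adjusted p = 0.0053, and adjusted p = 0.334 with an estimated correlation). Of 21 PPARγ targets, Gpihbp1, which carries lipoprotein lipase, and the lipase Lipe rose by 1.04 ± 0.21 and 1.04 ± 0.22, and Me1 fell by 1.08 ± 0.24; adjusted over the list alone, 6 rose and 3 fell (camera adjusted p = 0.0591).

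Between the 2 arrays of a group the median SD over probes was 0.202 in control chow and 0.153 in knockout chow. It was 0.113 in control and 0.128 in knockout on the diet. The model gives all groups 1 spread, so adjusted p for comparisons with control chow may be too small. Array weights were 0.54 for each control chow array and 1.61 for each control diet array. The limma fit called 663 probes on chow, 294 higher and 369 lower in knockout. The count was 0 without control chow replicate 1 (2251 at an unadjusted p under 0.05), 12 without knockout chow replicate 2, 348 without knockout chow replicate 1, 383 without a filter, 1014 with trend and robust estimation and 41 with array weights, which were chosen after seeing the data.

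On the atherogenic diet the knockout differed from control in 4 genes. Mt1 rose by 2.39 ± 0.19 (adjusted p = 3.09e-04), Rbp7, a retinol-binding protein, fell by 1.93 ± 0.23 (adjusted p = 0.0088) and Ldoc1 was at least 4.40-fold lower (adjusted p = 6.14e-05). The fourth was Pparg, by ILMN_1221594. On chow all 4 had an adjusted p under 0.05 in the same direction, with Rbp7 at −0.88 ± 0.23 (adjusted p = 0.0485) and Ldoc1 at least 1.47-fold lower. Rbp7 passed under 12 of the 18 alternatives on the diet and under 7 of 18 on chow, and the other 3 genes passed under all 18 on the diet. The 8 smallest p-values in each direction took in the 4 genes that passed. Among the rest, which did not pass, Abhd1 had a difference of 1.49 ± 0.24 (adjusted p = 0.135). Egr4, an immediate-early transcription factor, had −2.06 ± 0.34 (adjusted p = 0.135). Pou3f1, detected on 1 of 2 control arrays, had 1.38 ± 0.30 (adjusted p = 0.547). Vwa3a, detected on 1 of 2 knockout arrays, had −1.33 ± 0.25 and Rnase6 had −1.08 ± 0.21 (adjusted p = 0.347 each). Nudt12 and H4c9, lower in knockout, and Ppm1f, Ebna1bp2, Lag3, Gmppb and Mab21l2, higher, made up the others (adjusted p from 0.295 to 0.547). Ptgis differed by 0.06 ± 0.22 and Ptgs2 by −0.83 ± 0.37 (adjusted p = 1.00 and 0.947), and the prostanoid list had camera adjusted p = 0.983.

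In the lists that passed camera on the diet, 0 members were called over all genes. Immediate-early and heat-shock genes were lower, with a median of −0.36 and 5 of 25 members above 0 (adjusted p = 5.13e-08, and adjusted p = 0.254 with an estimated correlation). Medians were lower for macrophage markers (−0.30), fibroblast markers (−0.22), endothelial activation (−0.14) and sterol efflux genes (−0.11), with adjusted p of 0.0034, 0.0034, 0.0052 and 0.0419, and adjusted p = 0.254 with an estimated correlation for each. Cardiomyocyte markers had a median of −0.25 (adjusted p = 1.19e-05, and adjusted p = 0.502 with an estimated correlation). Proliferation genes were higher, with a median of 0.27 and 18 of 22 members above 0 (adjusted p = 4.51e-05, and adjusted p = 0.254 with an estimated correlation). PPARγ targets had a median of −0.036, which turned to 0.019 under median scaling and was −0.059 relative to the median of all probes, 0.078 with that scaling (adjusted p = 0.0181, and adjusted p = 0.502 with an estimated correlation). Plin4, the single measured adipocyte marker and also a member of the PPARγ target list, was detected on 1 of 2 knockout arrays and had a difference of −0.73 ± 0.22 (camera adjusted p = 0.0181, and adjusted p = 0.254 with an estimated correlation). Adjusted over the list alone, 1 member was lower in each of these last 2 lists and 0 members passed in the other 7. Leaving out knockout diet replicate 1 turned the fibroblast median to 3.47e-04 (adjusted p = 0.398), and the sterol efflux call was lost without 7 of the 8 arrays in turn. The limma fit called 1 probe higher and 3 lower, and 702 had an unadjusted p under 0.05, near the 675 expected with no change. The genotype changes on the 2 diets, which share no array, correlated across probes at r = 0.238 (−0.0017 in simulated unchanged groups), and 76.3% of the 663 chow calls had the same sign on the diet. The simulated probes varied independently, so the simulated value is no reference for probes that vary together between pools.

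In control cells the diet raised Angptl4, a fatty-acid-induced inhibitor of lipoprotein lipase, by 3.16 ± 0.24 (adjusted p = 2.94e-04), and Ptgis fell by 2.22 ± 0.22 (adjusted p = 4.50e-04). Other large rises were in Adamts4, a proteoglycan-cleaving protease (2.84 ± 0.25), Phf11a (2.40 ± 0.28), Lpar4, a lysophosphatidic acid receptor (2.04 ± 0.20), Esm1, a proteoglycan secreted by endothelium (1.98 ± 0.19), Esrrb (1.94 ± 0.22), the chemokine Ccl5 (1.88 ± 0.24), Pkig (1.85 ± 0.23) and Sipa1 (1.84 ± 0.24). Mycl and Fam124b were at least 3.47-fold and at least 2.38-fold higher. Named falls, besides the clock genes below, were those of the aldehyde dehydrogenases Aldh3a1 (−2.49 ± 0.24) and Aldh1a1 (−2.35 ± 0.25), Esr1 (−2.30 ± 0.26), Cyp1b1 (−2.29 ± 0.24), Gal3st2 (−2.22 ± 0.40), Spon1 (−2.18 ± 0.23), Hamp, encoding hepcidin (−2.16 ± 0.25), and Degs2 (−2.13 ± 0.20). Isl1 was at least 2.62-fold lower. Esrrb was detected on 1 of 2 control chow arrays and Esr1 on 1 of 2 control diet arrays. The genes of this paragraph passed under all 18 alternatives, except Fam124b (14), Isl1 (16, with no value in the other 2) and Gal3st2 (17).

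**Figure D3:**
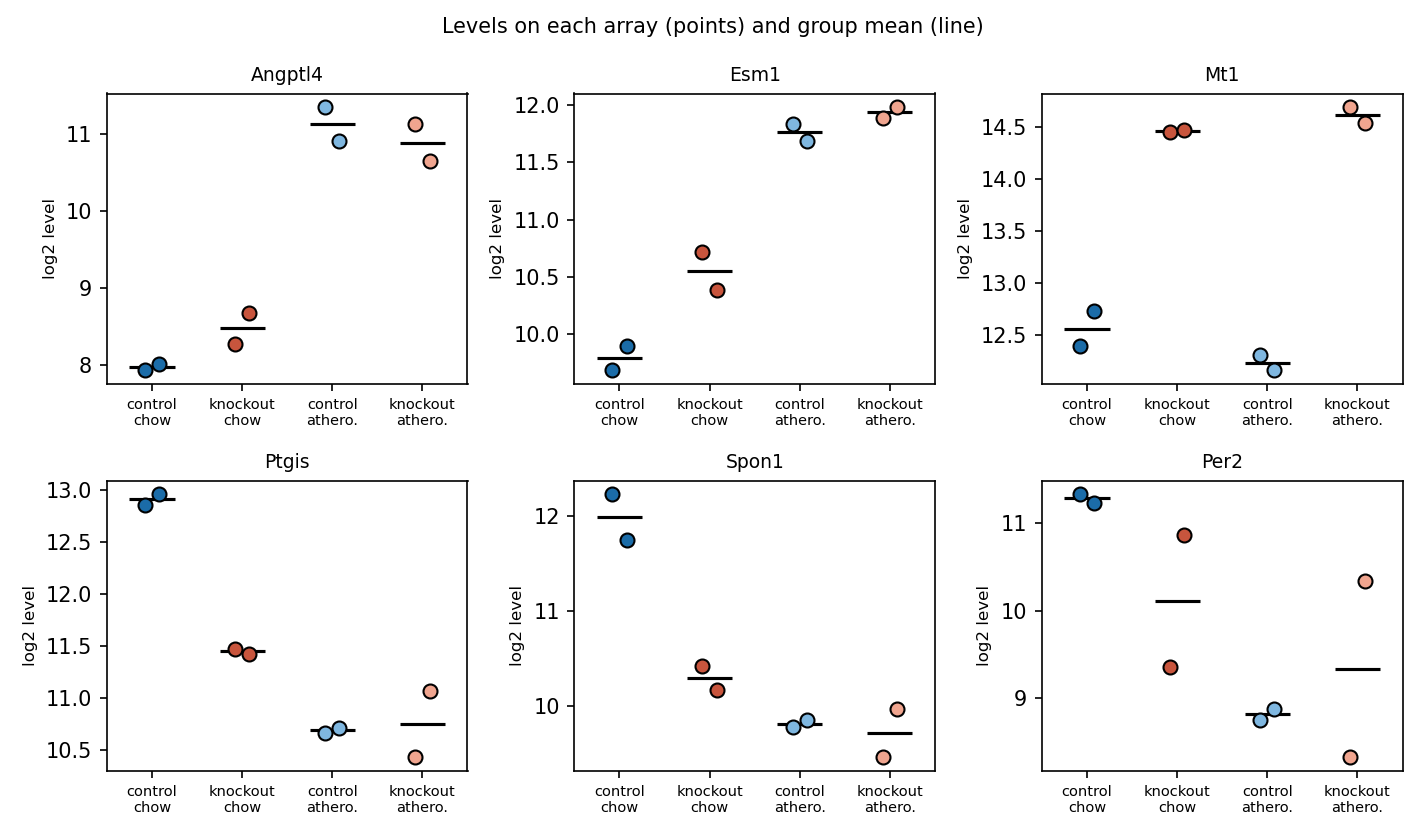
Normalized log2 level of 6 named genes on each array (points) with the group mean (line); the vertical axes do not start at 0 and differ between panels. Angptl4 has a mean of 7.97 in control chow and 11.13 in control on the diet, and Ptgis has 12.91 and 10.69.

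In the prostanoid list 1 of 16 members rose with the diet in control and 5 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.394). Besides Ptgis these were Slco2a1 (−1.37 ± 0.23), the epoxide hydrolase Ephx2 (−1.67 ± 0.28), Ptgs2 (−1.86 ± 0.37), the prostaglandin-degrading Hpgd (−1.95 ± 0.42) and, rising, the leukotriene C4 synthase Ltc4s (1.14 ± 0.21). Of 21 PPARγ targets 6 rose and 2 fell (9 and 2 adjusted over the list alone), the rises including Angptl4, Fabp3 (1.71 ± 0.21), Aqp7 (1.26 ± 0.19) and Gpihbp1 (1.34 ± 0.21), with camera adjusted p = 0.0060, and adjusted p = 0.426 with an estimated correlation. In the activation list 5 of 28 rose, with Ccl5 and Cxcl9 (1.37 ± 0.18) among them, and Vcam1 and Selp fell (−1.05 ± 0.21 and −1.41 ± 0.30); adjusted over the list alone, 6 rose and 3 fell (camera adjusted p = 0.174). Among 21 vascular tone genes 2 rose and 5 fell (2 and 6 adjusted over the list alone), with Npr3, the natriuretic peptide clearance receptor, at −1.83 ± 0.26 and Apln, encoding apelin, at 1.76 ± 0.28 (camera adjusted p = 0.138). Of 30 endothelial identity genes 3 rose and 3 fell (3 and 4 adjusted over the list alone): Ly6c1 (0.95 ± 0.20), Sox17 (0.88 ± 0.21) and Robo4 (0.64 ± 0.18) against Plvap (−1.23 ± 0.19), Vwf (−1.20 ± 0.20) and Eng (−0.66 ± 0.18), with camera adjusted p = 0.472.

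Of 22 proliferation genes 14 rose with the diet in control (16 adjusted over the list alone), among them Birc5 (1.78 ± 0.21), Cdk1 (1.58 ± 0.20), Tk1 (1.42 ± 0.19) and Cenpa (1.14 ± 0.18), with adjusted p = 2.47e-10, and adjusted p = 0.184 with an estimated correlation. Of 26 interferon-stimulated genes 9 rose (13 adjusted over the list alone), among them Oasl1 (1.66 ± 0.19) and Rsad2 (1.43 ± 0.19), with adjusted p = 1.01e-06, and adjusted p = 0.406 with an estimated correlation. Respiratory chain genes had a median of 0.28, with 1 of 46 called and 0 adjusted over the list alone (adjusted p = 2.99e-04, and adjusted p = 0.709 with an estimated correlation). In the matrix list 5 of 24 rose and 7 fell (7 and 8 adjusted over the list alone), with the basement membrane genes Col4a2 (1.54 ± 0.18) and Col15a1 (1.68 ± 0.23) and Sparc (1.25 ± 0.19) higher and the proteoglycan Bgn at −1.21 ± 0.20 (camera adjusted p = 0.759).

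Markers of other cells also differed with the diet in control. Cardiomyocyte markers rose in 12 of 24 cases (15 adjusted over the list alone), with Actc1 at 1.22 ± 0.23 (adjusted p = 2.30e-05, and adjusted p = 0.426 with an estimated correlation). Smooth muscle and pericyte markers rose in 8 of 16 (10 adjusted over the list alone), with Higd1b at least 2.70-fold higher and Rgs4 at 0.98 ± 0.21 (adjusted p = 2.30e-05, and adjusted p = 0.414 with an estimated correlation). Fibroblast markers fell in 9 of 17, with Lum at −1.64 ± 0.21, Dcn at −1.08 ± 0.19 and Postn, detected on 1 of 2 control diet arrays, at −1.87 ± 0.36; adjusted over the list alone, 1 rose and 10 fell (adjusted p = 3.10e-05, and adjusted p = 0.388 with an estimated correlation). Of 5 mesothelial markers 4 fell, with Upk3b at −1.47 ± 0.23, and Wt1 rose by 1.14 ± 0.20, with the same counts adjusted over the list alone (adjusted p = 0.0368, and adjusted p = 0.414 with an estimated correlation).

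Of 14 clock genes 2 rose and 5 fell (2 and 10 adjusted over the list alone). Arntl, the clock activator BMAL1, rose by 2.25 ± 0.61 and Nfil3 by 1.27 ± 0.29, while Ciart, Per2 and Tef had changes of −2.00 ± 0.36, −2.48 ± 0.56 and −2.14 ± 0.49 (camera adjusted p = 0.0046, and adjusted p = 0.422 with an estimated correlation). Arntl passed under 11 of the 18 alternatives (adjusted p up to 0.231), and Per2 and Tef under 13 each (up to 0.161 and 0.155). The call for Arntl was lost without each of the 4 control arrays in turn, at 2.37 and 2.15 without control chow replicates 1 and 2 and 2.15 and 2.35 without those on the diet. The calls for Per2 and Tef were lost without control chow replicate 1 (−2.44 and −1.95), control chow replicate 2 (−2.53 and −2.33) and control diet replicate 1 (−2.42 and −2.04). Knockout arrays of a group differed in such genes, with an SD of 1.08 for Per2 in knockout chow and 1.43 in knockout on the diet.

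Diet in control also uses the control chow arrays, to which the model gives the spread shared by all groups. The limma fit called 1494 probes for it, 734 higher and 760 lower, against 1071 calls with array weights. The count was 659 without control chow replicate 1, 502 without control diet replicate 1 and 619 without control diet replicate 2.

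**Figure D4:**
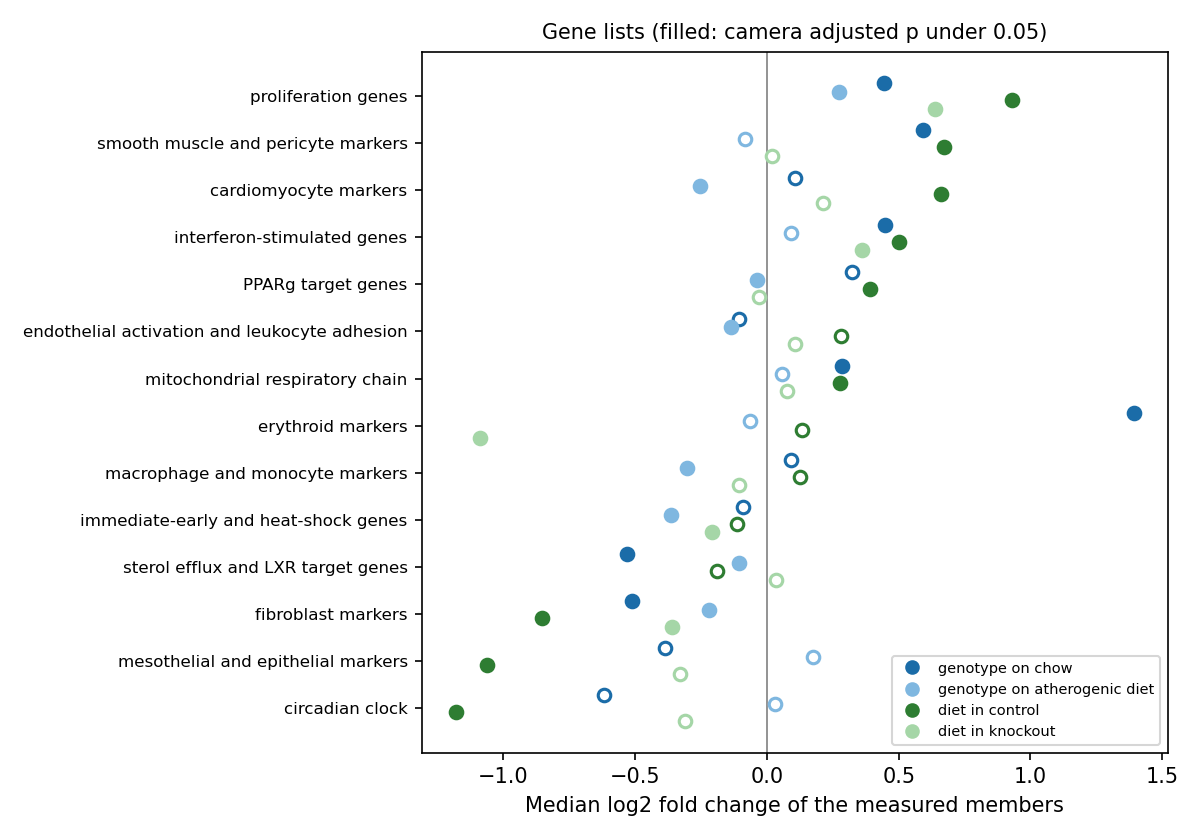
Median log2 change of the measured members of gene lists that passed camera in any of 4 comparisons (colours). The adipocyte list, with a single measured marker, is left out. Filled points mark an adjusted p under 0.05 with the preset correlation. Proliferation genes have medians of 0.93 for diet in control and 0.64 for diet in knockout; PPARγ targets by genotype on the atherogenic diet, at −0.036, turn to 0.019 under median scaling, which is −0.059 relative to the median of all probes.

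In knockout cells the diet raised Angptl4 by 2.41 ± 0.24 (adjusted p = 0.0054) and Sdcbp2, detected on 1 of 2 chow arrays, by 1.68 ± 0.28. Phf11a, by another probe than the one named for control, rose by 1.42 ± 0.23. The muscle stress protein Ankrd1 rose by 1.42 ± 0.23 and Esm1 by 1.39 ± 0.19. Pclaf and Ccna2, genes of DNA replication and the cell cycle, rose by 1.29 ± 0.21 and 1.23 ± 0.20, Upp1 by 1.22 ± 0.19, Ch25h, cholesterol 25-hydroxylase, by 1.09 ± 0.18 and Plau, urokinase, by 1.07 ± 0.18. Ms4a6b was at least 1.91-fold higher. Falls were found for Egr4 (−2.02 ± 0.34), Ephx2 (−1.65 ± 0.28), Hbb-bt (−1.62 ± 0.27), the plasma protein Ahsg (−1.62 ± 0.21), the mesothelial marker Upk3b, detected on 1 of 2 diet arrays (−1.37 ± 0.23), Mfap2 and Lox, which serve elastic matrix (−1.29 ± 0.20 and −1.28 ± 0.21), Itgbl1 (−1.23 ± 0.20), Hey2, a Notch target (−1.18 ± 0.20), and the platelet chemokine Ppbp (−1.16 ± 0.19). Of these genes Angptl4, Ahsg and Esm1 had an adjusted p of 0.0054, 0.0378 and 0.0421 and all others of 0.0489. Of the 18 alternatives Angptl4 passed under 13, Ahsg under 11 and the others under 5 to 8. Ptgis differed by −0.70 ± 0.22 (adjusted p = 0.213).

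Proliferation genes were higher after the diet in knockout, with 22 of 22 members above 0 and a median of 0.64; 1 was called, and 16 adjusted over the list alone (adjusted p = 1.01e-15, and adjusted p = 0.0850 with an estimated correlation). Interferon-stimulated genes had a median of 0.36, with 0 of 26 called and 1 adjusted over the list alone (adjusted p = 2.70e-04, and adjusted p = 0.422 with an estimated correlation). Erythroid markers were lower, with a median of −1.09 and Hbb-bt called among 5, and 5 adjusted over the list alone (adjusted p = 1.27e-08, and adjusted p = 0.295 with an estimated correlation). The high group was knockout chow, with means of 11.02 for Hbb-bt and 15.38 for Hba-a1. Means were 9.39 and 14.23 in knockout on the diet, 9.08 and 13.99 in control chow, and 9.48 and 14.30 in control on the diet. This erythroid fall, the erythroid rise by genotype on chow and the interaction all use the knockout chow arrays. Fibroblast markers had a median of −0.36, with 0 of 17 called and 6 lower adjusted over the list alone (adjusted p = 1.71e-05, and adjusted p = 0.295 with an estimated correlation). Immediate-early genes had a median of −0.21, with 0 of 25 called and 1 adjusted over the list alone (adjusted p = 0.0037, and adjusted p = 0.422 with an estimated correlation). Diet changes in control and knockout, which share no array, correlated across probes at r = 0.508 (0.0010 in simulated unchanged groups), and 87.3% of the 1494 control calls had the same sign in knockout. Here too the simulated probes varied independently, so the simulated value is no reference for probes that vary together between pools.

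The limma fit called 24 probes for diet in knockout, 13 higher and 11 lower, and 1403 had an unadjusted p under 0.05 (675 expected). The count was 0 without control chow replicate 1, control chow replicate 2 or knockout diet replicate 1 (1740, 1739 and 855 at an unadjusted p under 0.05), 8 and 1 without knockout chow replicates 1 and 2, 2 without either control diet replicate and 10 without knockout diet replicate 2. It was 0 without a filter and with only the compared groups (2092 and 1495 unadjusted), 5 with the replicate block, 43 with array weights, 70 with median scaling, 79 with the strict filter, 135 with an offset of 50, 148 without background correction, 157 with the authors' table and 181 with trend and robust estimation.

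The interaction asked whether the diet change differed by genotype. No gene passed, and the 8 smallest p-values in each direction are named here. With positive values these were Adh7, Gpm6a, Efna5, Bst1, Lag3, Isl1, Wnt5a and Trerf1; Efna5 (1.65 ± 0.26, adjusted p = 0.0877) alone was detected in all groups, and no value is given for the others. With negative values they were Ppbp (−1.74 ± 0.26), the chromatin protein Hmgb2 (−1.86 ± 0.29), the histone H4c9 (−1.78 ± 0.30), Sipa1 (−1.94 ± 0.33), Cav2, a caveolar protein (−1.62 ± 0.28), Zfp985 (−1.39 ± 0.25), and Spon2 and Ldoc1, each undetected in at least 1 group. Ptgis had an interaction of 1.52 ± 0.31 (adjusted p = 0.176), so its larger fall in control than in knockout was not a called difference. The limma fit called 0 probes, with a smallest adjusted p of 0.0812, and it called 36 with trend and robust estimation. In the main fit 1398 probes had an unadjusted p under 0.05 (675 expected). By camera 7 of 30 lists passed, all with negative medians, and 0 did with an estimated correlation. In these lists 0 members were called over all genes. Adjusted over the list alone, 7 smooth muscle, 5 erythroid, 4 PPARγ target, 2 macrophage and 1 interferon-stimulated gene had negative values, 1 PPARγ target had a positive value and 0 cardiomyocyte and 0 respiratory chain genes passed.

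Averaged over the diets, Mt1 was higher in knockout by 2.14 ± 0.13, and Ptgs2 (−1.32 ± 0.26), Ptgis (−0.70 ± 0.15), Apoc1 (−1.07 ± 0.21) and Apoe (−0.79 ± 0.16) were lower. Ptgis was −1.46 on chow and 0.06 on the atherogenic diet (adjusted p = 1.00). Proliferation genes were higher, with a median of 0.35, 1 of 22 called and 8 adjusted over the list alone (adjusted p = 7.81e-08, and adjusted p = 0.252 with an estimated correlation). Erythroid, interferon-stimulated, smooth muscle and respiratory chain lists were higher too, with medians of 0.66, 0.24, 0.17 and 0.16 and adjusted p of 2.27e-05, 2.27e-05, 0.0123 and 8.53e-05 (adjusted p = 0.316, 0.316, 0.452 and 0.763 with an estimated correlation). On the atherogenic diet alone the erythroid and smooth muscle medians were −0.066 and −0.084 (camera adjusted p = 0.698 and 0.169), against 1.39 and 0.59 on chow. The interferon-stimulated and respiratory chain lists, with medians of 0.45 and 0.29 on chow, did not pass camera on that diet either. Fibroblast, immediate-early and sterol efflux lists were lower, with medians of −0.42, −0.23 and −0.24 and adjusted p of 3.27e-05, 2.00e-04 and 0.0017 (adjusted p = 0.252, 0.278 and 0.252 with an estimated correlation). Called members numbered 2 erythroid, 0 interferon-stimulated, 1 smooth muscle and 0 respiratory chain genes higher, and 2 fibroblast, 3 immediate-early and 3 sterol efflux genes lower; adjusted over the list alone they were 5, 4, 4, 0, 7, 4 and 5. The limma fit called 206 probes, 76 higher and 130 lower. That count was 3 without control chow replicate 1, 4 without knockout diet replicate 1, 20 without knockout chow replicate 2, 19 and 17 without control diet replicates 1 and 2, and 129 without knockout diet replicate 2.

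The chow genotype change and the diet change in control share both control chow arrays. Of their calls, 204 were higher in both and 310 lower in both, where independent lists would share 15.98 and 20.8. Across probes the changes correlated at r = 0.801, against 0.499 in simulated unchanged groups set against the same control arrays, with a covariance of 0.164 against 0.0252. The simulated groups all had the same spread, which fixes the simulated r in advance. Control chow had a wider spread between its arrays, with a median SD of 0.202, against 0.153 in knockout chow and 0.113 in control on the diet. The simulated r is therefore no reference here, and the simulated covariance may be too low. The controls could not be split with 2 arrays in each part, so how much of the correlation comes from the shared control arrays could not be told.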

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

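The tests of an even dilution, of directions within levels and of different kinds of other cells were chosen after the results were seen. For 7 of the 30 gene lists the diet change differed between genotypes by camera's test of the interaction, with lower values in knockout than in control. The medians were −0.77 for smooth muscle and pericyte markers, −1.12 for erythroid markers, −0.32 for cardiomyocyte markers, −0.36 for PPARγ targets, −0.31 for interferon-stimulated genes, −0.20 for respiratory chain genes and −0.49 for macrophage markers. Adjusted p ran from 6.14e-07 to 0.0375, and from 0.430 to 0.787 with an estimated correlation. Median scaling moved the median of all probes in the interaction to −0.11. Among PPARγ targets, Aqp7 had −1.41 ± 0.27 and Gpihbp1 −1.31 ± 0.29 (limma adjusted p = 0.147 and 0.198).

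These medians use all groups, and they and the genotype calls on chow include the control chow arrays, which stood apart from the other 6. For erythroid genes the high group was knockout chow. Hbb-bt had group means of 9.08 in control chow, 11.02 in knockout chow, 9.48 in control on the diet and 9.39 in knockout on the diet. Hba-a1 had 13.99, 15.38, 14.30 and 14.23 in the same order. The tests below concern the control chow arrays and do not cover this. An even dilution of the endothelial cells by all other cells is argued against, since fibroblast markers fell while cardiomyocyte and smooth muscle markers rose, with a gap of 1.53 between list medians. The control chow arrays had a mean signal of 719, against 883 in control on the diet. Lower brightness as the whole cause is argued against: it would move probes of one level one way, but under median scaling 25.1% of the probes called for diet in control moved against the majority among probes of like mean level (10 bins of equal size), and at least 13.8% in each bin. Under median scaling the share of higher calls rose with level, from 49 of 115 in the lowest bin to 228 of 271 in the highest. Brightness as part of the cause therefore stays open. After quantile normalization the trend of change with level over the called probes had a Spearman rho across probes of 0.0154. That value decides nothing, because this step gives every array the same distribution. A test of other cells as the source of changes in endothelial identity genes was dropped after its values were seen, as neither of its conditions was met: 3 called identity genes rose and 3 fell. Different kinds of other cells in the control chow preparations stay open: 4 of 10 marker lists of other cells passed camera for diet in control, 2 higher and 2 lower, and 0 of the 4 passed with an estimated correlation (adjusted p from 0.388 to 0.426). Abundant members had group means in control chow and control on the diet of 15.30 and 14.22 (Dcn), 12.45 and 12.95 (Acta2) and 11.65 and 11.94 (Atp2a2). Other lists held 0 of the 24 cardiomyocyte, 17 fibroblast, 16 smooth muscle and 5 mesothelial markers. Such cells may account for part of the pattern; how the endothelial cells were isolated or sorted is not given in the sources used here, and effects of genotype, diet and age stay open as untested.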

How the results depend on the processing

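Array weights were chosen after seeing the data. For diet in knockout (24 calls), the count was 148 without background correction, 70 with median scaling, 157 with the authors' table, 135 with an offset of 50, 0 without a filter (2092 at an unadjusted p under 0.05), 79 with the strict filter, 0 with only the compared groups (1495 unadjusted), 181 with trend and robust estimation and 43 with array weights. The averaged genotype count (206) was 471, 364, 497, 493, 49, 424, 552 and 115 in the same order, without the compared-groups setting. The interaction (0 calls by limma, 1398 unadjusted) gave 16, 12, 20 and 20 with the first 4 settings, 6 with the strict filter and 36 with trend and robust estimation. Genotype on chow (663) gave 383 without a filter, 1014 with trend and robust estimation and 41 with array weights, and genotype on atherogenic diet (4) gave 7 with each of the last 2. Leaving out each array gave 0 to 574 calls for genotype on chow, 3 to 4 for genotype on atherogenic diet, 502 to 1671 for diet in control, 0 to 10 for diet in knockout, 0 for the interaction and 3 to 176 for the averaged genotype; the lone array is then assumed to vary like the other groups. No filter tests more probes and leave-one-out has fewer arrays; for the other settings the cause was not tested.

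The replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated across probes between −0.052 and 0.137. A replicate block gave 636, 4, 1415, 5, 0 (1441 unadjusted) and 168 calls for genotype on chow, genotype on atherogenic diet, diet in control, diet in knockout, the interaction and the averaged genotype. Median scaling moved the median of all probes to 0.18 for genotype on chow and for diet in control and to 0.13 for the averaged genotype, and the share of higher calls from 44.3% to 76.0%, from 49.1% to 74.1% and from 36.9% to 74.2%. For diet in knockout the share went from 54.2% to 71.4% and for genotype on atherogenic diet from 25.0% to 40.0%. For the interaction, with 0 calls before, 16.7% of calls were higher.

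Of 2329 values of named genes under the alternatives, 1897 kept direction and side of the threshold, 371 no longer passed, 56 newly passed and 5 changed sign. The 5 had not passed, and the cause was not tested. Leaving out each array, Pparg for diet in knockout ranged from −0.45 to 0.13 by ILMN_1221060 and from −0.036 to 0.18 by ILMN_1221594, which was undetected in knockout, Ptgis for genotype on atherogenic diet from −0.26 to 0.37, and Selp for diet in knockout from −0.63 to 0.20, with 0.099 without knockout diet replicate 1. Of 45 gene list calls, 0 held with an estimated correlation, 43 with the authors' table and 45 with the replicate block. Without replicates 1 and 2 of a group, 37 and 40 held for control chow, 45 and 41 for knockout chow, 38 and 43 for control on the diet and 39 and 42 for knockout on the diet. Pparg by ILMN_1221594 passed for genotype on atherogenic diet under all 18 alternatives (adjusted p from 1.38e-04 to 0.0341). Probes near background are limited by their signal over it.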

Other observations

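The arm test of the clock genes was set after the clock list's change had been seen, and the count of Pparg's neighbours called on chow, the clock arms in other comparisons and without each array and the naming of Ldoc1 and Rbp7 for diet were chosen after their values were seen. In control cells Ldoc1 rose with the diet by 1.54 ± 0.18 and Rbp7 by 1.61 ± 0.23 (limma adjusted p = 7.22e-04 and 0.0016). In knockout cells Rbp7 differed by 0.56 ± 0.23 (adjusted p = 0.383), with an interaction of −1.05 ± 0.32 (adjusted p = 0.288). Ldoc1 was detected on 0 of the 4 knockout arrays, so its diet change there and its interaction could not be measured. Among haemostasis genes the ectonucleotidase Entpd1, which degrades extracellular ATP and ADP, had −1.23 ± 0.21 for genotype on chow and −1.61 ± 0.21 for diet in control, and Plau had 0.72 ± 0.18 and 1.70 ± 0.18, all called.

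The remaining lists did not pass camera for diet in control. Adjusted p was 0.759 for angiogenesis, 0.190 for haemostasis, 0.190 for sterol efflux, 0.229 for macrophage, 0.872 for lymphocyte, 0.138 for neutrophil, 0.734 for erythroid, 0.899 for adipocyte and 0.138 for Schwann cell genes. It was 0.138 for antigen presentation, 0.616 for immediate-early genes, 0.394 for cholesterol synthesis, 0.699 for fatty-acid oxidation, 0.951 for oxidant enzymes, 0.394 for endoplasmic reticulum stress and 0.759 for sex-linked transcripts. For genotype on chow it was 0.428 for vascular tone, 0.632 for endothelial identity, 0.0980 for clock and 0.209 for matrix genes.

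Clock genes moved in opposite arms with the diet in control cells. The 3 measured genes of the first arm, Arntl, Clock and Nfil3, had a mean change of 1.34 (SD 0.88). The 8 of the other arm, Per1, Per2, Per3, Nr1d1, Nr1d2, Dbp, Tef and Ciart, had −1.69 (SD 0.63). The exact two-sided permutation p was 0.0061, the smallest that 165 permutations can give. Collection at another time of day may account for this, and so may a change of clock phase with the diet; the test does not separate them, and collection times are not given in the sources used here. The permutation is over genes and does not cover the spread between arrays; without each array in turn the arms stayed apart in control, with 1.25 to 1.43 and −1.79 to −1.60. For genotype on chow the arms had means of 0.75 and −0.87, and 0.30 and −0.46 without knockout chow replicate 1. For diet in knockout they had 0.22 and −0.59, but the arrays of a group disagreed. Per2 was 8.31 and 10.33 in replicates 1 and 2 on the diet, and 9.35 and 10.87 in those on chow. Without knockout diet replicate 1 the arms turned, to −0.40 and 0.23.

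The 206 calls for the averaged genotype were set against other splits of the 8 arrays, with 2 of the 4 arrays of each diet in each part. Of 18 splits 1, the real split, gave as many, and the highest of the others gave 33; 18 splits are too few for a share under 0.05.

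A strain segment carried along with the floxed Pparg allele would raise the share of changed genes near Pparg. Of the 40 nearest tested genes, 20 on each side in the order of GRCm38.p6, 15.0% had an unadjusted p under 0.05 for the averaged genotype. The share was 16.9% of 9325 other genes (one-sided Fisher's exact p = 0.691). This does not decide the question, because with 40 genes and such a share elsewhere a segment that changed a few genes could be missed. Of the 40, Ift122 alone was called for the averaged genotype (0.76, limma adjusted p = 0.0297). On chow 6 of the 40 were called, all higher in knockout, against 5.06% of the other genes. They were Syn2 (0.99, detected on 1 of 2 control chow arrays), Timp4 (1.79), Ift122 (1.05), Rassf4 (1.12), Depp1 (1.83) and Cxcl12 (0.77); on the atherogenic diet their values were 0.08, −0.13, 0.46, 0.24, 0.03 and 0.03, with 0 called.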
